A study of Mus musculus with 9 samples.

How the data were processed

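Ear tissue messenger RNA of C57 mice was measured in 9 libraries, 3 from control ears (absolute ethanol), 3 from ears treated with MC903 and 3 from mice given MC903 and paeonol at 200 mg/kg. Groups were read from the treatment label of each sample and replicate numbers from its title, and the columns of the file were joined to the samples by the library names in the labels. Per the labels' protocols, total RNA was extracted with Trizol, its integrity number was above 7.0, messenger RNA was selected with oligo(dT), and the second strand was marked with dUTP. Per the submitters' processing notes, cutadapt, HISAT2 2.0.4, StringTie 1.3.4d and the genome build GRCm38 were used; their roles, the annotation and the strand setting are not given in the sources used here.

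The file deposited by the authors holds whole numbers per gene that are taken here as estimated counts, not scaled between libraries. Low values pile up at multiples of 4: the value 4 is 1.90 to 2.23 times as frequent as the mean of its neighbours, and the value 8 is 1.23 to 1.49 times. How whole numbers were made from the StringTie output is not given in the sources used here. For this reason the floor for a group without counts was set at 12 counts per library, which is 3 times 4. Where a group had counts at a mean of up to 12 per library, called changes are given as ratios with exact Poisson 95% intervals on counts divided by 4. These intervals and the floor cover counting error only. Library totals were 54.26 to 57.75 M estimated counts. Of 55401 features, 55141 matched a GENCODE M21 symbol, 33888 had any count and 21925 passed edgeR's filterByExpr (minimum count 10, minimum total 15); 0.04% of the counts lay outside the genes tested. No value column was left unused.

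The 9 libraries were fitted together in edgeR 4.0.16 under R 4.3.3 and data.table version 1.17.8 with TMM scaling (factors 0.942 to 1.09), a robust quasi-likelihood fit and 1 coefficient per group. The common biological coefficient of variation was 0.214. The 3 pairs of groups were each compared with the quasi-likelihood F test, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The standard error of a log2 change was approximated from the change and its F value. Principal components were taken from log2 CPM with a prior count of 2. Opposite changes were counted as genes called in MC903 versus control and called with the other sign in MC903 with paeonol versus MC903. They were set beside 20 simulations of unchanged groups that share the MC903 libraries (seed 20240601).

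Gene lists (31, with 582 genes, of which 575 matched and 551 were tested) were fixed before the data were examined. Each was tested with camera from limma 3.58.1 on the edgeR fit, with a preset correlation of 0.01 and adjustment over the 31 lists. Members past the threshold were counted over all genes and adjusted over the list alone. Named genes follow a rule fixed at the same time. In every comparison they are Trpv3, Ccl3, Nfkb1, Rela, Nfkbia, Ccr1, Cyp24a1, Tslp, Il4 and Il13. To these were added the 5 largest changes in each direction among called genes with a mean log2 CPM of at least 2 and groups without overlap, and the 2 members with the smallest p in each of the 12 lists with the smallest camera p. For opposite changes the 5 largest products of the log2 changes were taken. Symbols of predicted genes and features without a symbol were left out of the largest changes. Some genes that the rule takes are not reported here.

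Alternatives fixed in advance were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter at a mean CPM of 1, fits of 2 groups, a minimum of 2-fold, the replicate number as a block, a covariate made from the skeletal muscle list, camera with an estimated correlation, fry, each library left out, and genes chosen and measured with different MC903 libraries. Counts divided by 4 and scaling by library totals alone were added after the data were seen. The calling was tested on simulated data made from these libraries, in the fit of MC903 versus control. Of genes changed 1.5-fold, 2-fold and 4-fold, 31.3%, 70.1% and 93.9% were recovered with the right sign, and 0.0427% of 21065 unchanged genes were called. Of 100 genes simulated to return to control, 60 were called as opposite changes, against 3 of the unchanged genes. For a list shifted 1.5-fold the camera p was 3.12e-33 on the simulated data, and for an unshifted list 0.441. Genes were simulated independently of each other, so these values do not show how camera behaves on correlated genes. On counts divided by 4, replicates within a group differed by a chi-square per degree of freedom of 7.03 to 15.8, more than counting noise if 4 counts stand for 1 fragment.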

Results

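Messenger RNA from the ears of C57 mice was sequenced in 9 libraries, 3 in each of 3 groups. Control ears received absolute ethanol. The MC903 ears received calcipotriol (MC903), a vitamin D analogue whose application to mouse skin is widely used as a model of atopic dermatitis. The third group received MC903 and paeonol, a phenolic compound of peony root bark, at 200 mg/kg. The series title names the channel TRPV3, the transcription factor NF-κB and the chemokine CCL3 in keratinocytes as the path under study. The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. All 9 libraries entered a single edgeR quasi-likelihood fit of 21925 genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE). Expression is in CPM, counts scaled to the TMM-adjusted size of each library, as mean ± SD over n = 3 libraries.

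The 3 groups lay apart on the first 2 principal components of log2 CPM. The first component held 43.7% of the variance and the second 15.9%. On the first, the controls lay between -80.2 and -71.6 and the MC903 libraries between 81.0 and 91.3. The paeonol libraries lay between them, from -17.0 to 3.36. On the second component the paeonol libraries lay below both other groups, from -71.9 to -39.6.

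**Figure D1:**
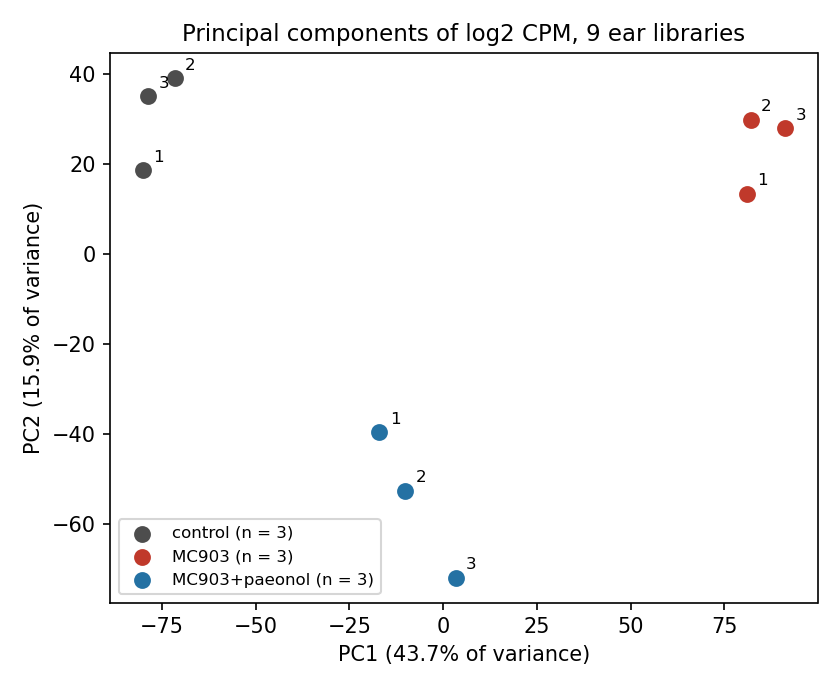
Each point is 1 library, placed by its first (43.7% of the variance) and second (15.9%) principal components of log2 CPM, coloured by group, with its replicate number beside it. The paeonol libraries lie between the control and MC903 libraries on the first component and below both on the second.

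The first comparison, MC903 against control, gives the response of the ear to the vitamin D analogue. Cyp24a1, the enzyme that degrades active vitamin D, was expressed at 9.99 ± 2.61 CPM in control ears and 4613 ± 314 CPM in MC903 ears (SD, n = 3), a log2 change of 8.85 ± 0.46. Tslp, the epithelial cytokine that starts type 2 inflammation in this model, went from 6.37 ± 0.599 to 1039 ± 384 CPM, a log2 change of 7.35 ± 0.45. Stress keratins, alarmins, proliferation genes and macrophage markers were mostly higher, and markers of skeletal muscle, fat, cartilage, nerve and sebaceous gland mostly lower. Of 21925 genes tested with edgeR's quasi-likelihood test, 10259 were called, 5044 higher and 5215 lower in MC903. That is 46.8% of the genes tested, and the median absolute log2 change of the called genes was 0.752. Scaling by library totals alone, an alternative added after the data were seen, moved the median log2 change of all genes from -0.0155 to -0.205 and the split to 3402 higher and 7224 lower.

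Trpv3, Ccl3 and Nfkbia, genes of the path named in the title, were higher in MC903. The libraries hold RNA of ear tissue with many cell types. Changes of these genes, here and in the later comparisons, therefore cannot be assigned to keratinocytes. Trpv3, a heat-sensitive cation channel of keratinocytes (GRCm38 chromosome 11, 73267388 to 73300363), went from 52.5 ± 4.89 to 179 ± 14.3 CPM (SD, n = 3). Its log2 change was 1.77 ± 0.13, with an edgeR adjusted p of 1.98e-06. Ccl3, a chemokine that draws monocytes and other leukocytes (chromosome 11, 83647844 to 83649355), went from 2.27 ± 0.926 to 16.2 ± 4.33 CPM, with a log2 change of 2.84 ± 0.34 and an edgeR adjusted p of 5.95e-05. Nfkbia, which encodes the NF-κB inhibitor IκBα and is itself an NF-κB target, rose by a log2 change of 1.17 ± 0.14. Of the NF-κB subunit transcripts, Nfkb1 rose by 0.24 ± 0.06 and Rela by 0.20 ± 0.06, and under scaling by library totals both calls ended, with log2 changes of 0.05 and 0.0064. Ccr1, a receptor for CCL3, rose by 2.01 ± 0.28. Il4 and Il13, the type 2 cytokines, were at 0.863 ± 0.229 and 0.0877 ± 0.0928 CPM in MC903 and were not called. With the skeletal muscle covariate, which nearly follows the group (R squared 0.92), the calls of Ccl3, Nfkbia, Ccr1, Nfkb1 and Rela ended (edgeR adjusted p = 0.37, 0.132, 0.543, 0.98 and 0.718).

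**Figure D2:**
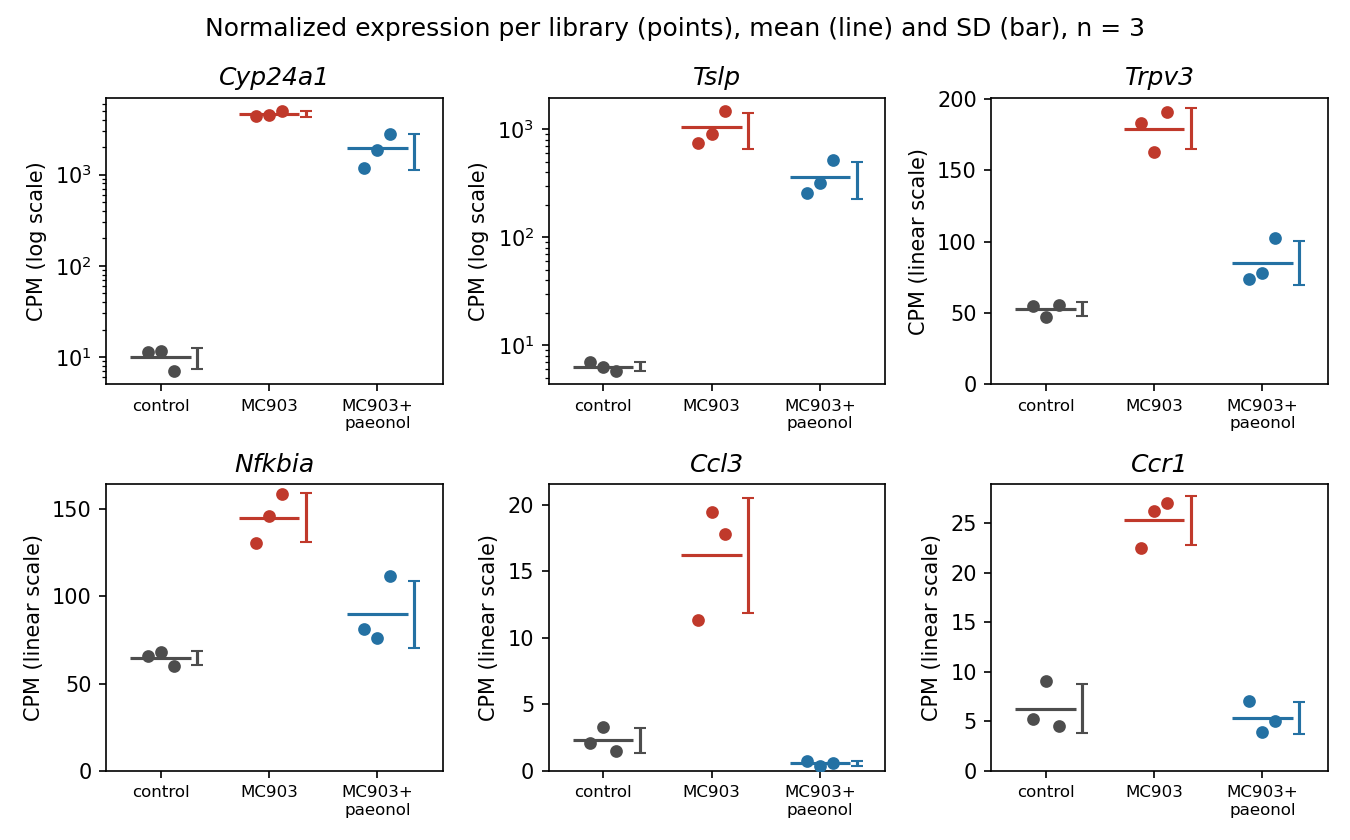
Each panel shows 1 gene's expression in CPM, on a log axis for Cyp24a1 and Tslp and a linear axis from 0 for the others, with 1 point per library, a line at the group mean and a bar of ± 1 SD (n = 3). For each of the 6 genes the MC903 mean is the highest of the 3 groups, and the paeonol mean of Ccl3 (0.538 CPM) lies below the control mean (2.27 CPM).

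Among the largest increases were 2 genes with no counts in any control library. AL805899.1, a feature on chromosome 4 (88909855 to 88938521) that contains the microRNA gene Mir31 on the same strand, reached 58.1 ± 3.61 CPM in MC903, at least 286-fold higher than a floor of 12 counts per library. S100g, a calcium-binding protein gene induced by vitamin D, reached 12.4 ± 2.83 CPM, at least 61.3-fold higher. Akr1d1, a steroid reductase, and Ecel1, an endothelin-converting enzyme family member, had only 6 to 9 and 0 to 14 estimated counts in the control libraries. Their ratios to control were 1040 (95% counting interval 479 to 2850) and 604 (277 to 1650). The calls of S100g and Ecel1 ended with the skeletal muscle covariate (edgeR adjusted p = 0.0648 and 0.0676). Rankings of the largest changes hold only among called genes with a mean log2 CPM of at least 2 and groups without overlap. Within these limits the largest decreases were in Serpina3b (-6.83 ± 0.32), the keratin Krt77 (-5.66 ± 0.69), Serpinb6d (-5.58 ± 0.36), the progestin receptor family gene Paqr7 (-5.38 ± 0.48) and the interleukin-1 family gene Il1f10 (-5.17 ± 0.37).

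Among the epidermal and growth lists fixed before the data were examined, stress keratins, alarmins and antimicrobial genes had 32 higher and 1 lower of 35 tested (32 and 1 adjusted over the list alone). The antimicrobial peptide gene Defb14 rose by 4.24 ± 0.28 and the alarmin Il33 by 0.95 ± 0.10. The cell cycle list had 28 higher and 0 lower of 30 tested (28 and 0 adjusted over the list alone). Among its members were the replication helicase gene Mcm5 (1.53 ± 0.10) and the spindle gene Tpx2 (1.08 ± 0.09). NRF2 antioxidant genes had 12 higher and 3 lower of 17 tested (13 and 3 adjusted over the list alone), with glutathione reductase Gsr at 2.31 ± 0.09 and sulfiredoxin Srxn1 at 1.84 ± 0.09. Vitamin D receptor targets had 7 higher and 2 lower of 13 tested (7 and 2 adjusted over the list alone), among them osteopontin, Spp1 (2.50 ± 0.17), and the calcium pump Atp2b1 (1.65 ± 0.13). The camera test with a preset correlation called these 4 lists, with adjusted p from 1e-16 to 0.000654, and the adjusted p was between 0.147 and 0.241 with an estimated correlation. Epidermal differentiation genes went both ways, with 10 higher and 15 lower of 31 tested (10 and 17 adjusted over the list alone), and their list was not called. The calls of Il33 and Spp1 ended with the skeletal muscle covariate (edgeR adjusted p = 0.106 and 0.122).

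Several immune lists were higher. Monocyte and macrophage markers had 16 higher and 2 lower of 20 tested (16 and 2 adjusted over the list alone), with the complement gene C1qa at 1.51 ± 0.14. Chemokines had 13 higher and 4 lower of 31 tested (15 and 4 adjusted over the list alone), and neutrophil markers 9 higher and 1 lower of 13 tested (10 and 1 adjusted over the list alone). The list of NF-kB members and targets had 16 higher and 4 lower of 30 tested (16 and 4 adjusted over the list alone); cyclooxygenase-2, Ptgs2, rose by 4.41 ± 0.30 and Nfkbiz by 1.15 ± 0.11. Mast cell and basophil markers had 8 higher and 2 lower of 15 tested (11 and 2 adjusted over the list alone), with histidine decarboxylase, Hdc, at 2.96 ± 0.14 and the basophil protease Mcpt8, with 0 to 6 estimated counts in the control libraries, at 32.7 times control (95% counting interval 10.8 to 161). Type 2 cytokines and receptors had 11 higher and 4 lower of 23 tested (12 and 4 adjusted over the list alone), and immediate early and heat shock genes 9 higher and 1 lower of 16 tested (9 and 1 adjusted over the list alone). In the type 2 list the cytokine genes Il5, Il9 and Il31 did not pass the expression filter, and Il4 and Il13 were not called. The camera test called these 7 lists, with adjusted p from 1.52e-06 to 0.0485, and the adjusted p was between 0.365 and 0.568 with an estimated correlation. The call of the type 2 list ended without MC903 library 3, control library 1 or control library 3 (camera on the edgeR fit, adjusted p = 0.0597, 0.105 and 0.0827). It also ended without the expression filter (0.0626 as camera adjusted p) and with counts divided by 4 (0.065). With the skeletal muscle covariate the calls of these lists other than NF-kB ended (camera adjusted p between 0.05 and 0.687), as did those of C1qa, Nfkbiz and Mcpt8 (edgeR adjusted p = 0.172, 0.0924 and 0.356).

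Markers of muscle, fat, cartilage, nerve and sebaceous gland were mostly lower in MC903. Skeletal muscle had 0 higher and 19 lower of 20 tested (0 and 20 adjusted over the list alone), with a median log2 change of -1.73; myoglobin, Mb, was at -1.39 ± 0.12 and titin, Ttn, at -1.27 ± 0.13. Adipocyte markers had 0 higher and 14 lower of 14 tested (0 and 14 adjusted over the list alone), with perilipin, Plin1, at -3.15 ± 0.19 and Adipoq at -2.36 ± 0.14. Cartilage had 0 higher and 12 lower of 14 tested (0 and 13 adjusted over the list alone), with Col11a2 at -2.21 ± 0.13 and Sox9 at -1.35 ± 0.09. Nerve and Schwann cell markers had 0 higher and 9 lower of 12 tested (0 and 9 adjusted over the list alone), with the myelin gene Mbp at -1.48 ± 0.07. Sebaceous gland genes had 0 higher and 15 lower of 18 tested (0 and 15 adjusted over the list alone). The lipid synthesis gene Dgat2 was at -1.63 ± 0.11 and Mgst1 at -1.61 ± 0.14. Dendritic and Langerhans cell markers had 4 higher and 8 lower of 17 tested (4 and 9 adjusted over the list alone), and fibroblast and matrix genes 5 higher and 9 lower of 19 tested (5 and 10 adjusted over the list alone). These 7 lists were called with camera adjusted p from 2.34e-12 to 0.0443, and the adjusted p was between 0.235 and 0.624 with an estimated correlation. Without MC903 library 1, paeonol library 1 or control library 2, the dendritic cell call (camera adjusted p = 0.0761, 0.0745 and 0.0916) and the fibroblast call (0.0935, 0.0985 and 0.0916) ended, and under scaling by library totals the dendritic cell call did (camera adjusted p = 0.0561). Both also ended with counts divided by 4 (camera adjusted p = 0.065 each) and in the fit of 2 groups (0.0873 and 0.0734), and the fibroblast call without the expression filter (0.0768). With the skeletal muscle covariate the list calls of skeletal muscle, sebaceous gland and dendritic cells ended (camera adjusted p = 0.861, 0.203 and 0.27). The calls of Mb, Ttn, Col11a2 and Mgst1 ended too (edgeR adjusted p between 0.0515 and 0.958). For the skeletal muscle list, Mb and Ttn this follows from the covariate, which is the mean of that list.

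The mitochondrially encoded genes had 7 higher and 0 lower of 13 tested (11 and 0 adjusted over the list alone), and their list was called higher (camera adjusted p = 0.0204, and adjusted p = 0.659 with an estimated correlation). That call ended under scaling by library totals (camera adjusted p = 0.0534). The other lists were not called. Their counts were 8 higher and 5 lower of 23 tested (8 and 5 adjusted over the list alone) for TRP channels and itch receptors, 4 higher and 2 lower of 16 tested (4 and 2 adjusted over the list alone) for type 17 and type 1 cytokines, and 4 higher and 0 lower of 24 tested (0 and 0 adjusted over the list alone) for interferon-stimulated genes. Tight junctions had 4 higher and 7 lower of 13 tested (5 and 7 adjusted over the list alone), and epidermal lipid barrier genes 9 higher and 5 lower of 24 tested (11 and 5 adjusted over the list alone). Endothelium had 4 higher and 3 lower of 12 tested (4 and 3 adjusted over the list alone), hair follicle genes 4 higher and 3 lower of 18 tested (4 and 3 adjusted over the list alone), and red blood cell genes 0 higher and 4 lower of 5 tested (0 and 4 adjusted over the list alone). T cells had 6 higher and 4 lower of 19 tested (7 and 4 adjusted over the list alone), and eosinophils 1 higher and 1 lower of 4 tested (1 and 1 adjusted over the list alone). No B or plasma cell marker of 10 tested was called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05. Tight junctions were called lower without MC903 library 1 (camera adjusted p = 0.0163). Interferon-stimulated genes were called higher without MC903 library 1 or 2 or control library 2 (0.0491, 0.0119 and 0.00173 as camera adjusted p) and under scaling by library totals (0.0195). For the hair follicle and B cell lists the sign of the median and the direction of the test differed.

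The list calls carry a limit, since the members of a list can move together. The counts of members called in a list share it, because those members are not independent results. With an estimated correlation, camera called 0 of the 31 lists in each of the 3 comparisons, while 6, 4 and 8 lists had an unadjusted p under 0.05 and the fry test called 22, 20 and 16. In other splits of the 6 libraries of a comparison, the camera test with a preset correlation called up to 21, 20 and 22 lists, against 17, 19 and 20 in the real splits of the same 2-group fits.

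The comparison of MC903 with paeonol against MC903 alone shows what differed when paeonol was given with MC903. No group received paeonol alone, and the labels name no vehicle of paeonol for the MC903 group. Effects of a vehicle or of handling by group therefore cannot be told apart from those of paeonol. Macrophage and neutrophil markers were mostly lower with paeonol, and epidermal differentiation and lipid barrier genes mostly higher. Chil3, a chitinase-like protein of activated macrophages, went from 76.8 ± 30.4 CPM in MC903 to 1.39 ± 0.913 CPM with paeonol (SD, n = 3), a log2 change of -5.77 ± 0.53. Slurp1, a secreted protein of late keratinocyte differentiation, went from 4.33 ± 1.74 to 84.1 ± 6.6 CPM, a log2 change of 4.28 ± 0.30. Of the 21925 genes, edgeR called 6502, 3357 higher and 3145 lower with paeonol, and the median absolute log2 change of the called genes was 0.617.

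Trpv3 fell from 179 ± 14.3 to 84.9 ± 15.6 CPM (SD, n = 3), a log2 change of -1.08 ± 0.12 with an edgeR adjusted p of 0.000124. Ccl3 fell from 16.2 ± 4.33 to 0.538 ± 0.19 CPM, a log2 change of -4.91 ± 0.39 with an edgeR adjusted p of 1.45e-05. Nfkbia fell by a log2 change of 0.70 ± 0.13. The subunit transcripts Nfkb1 and Rela had log2 changes of -0.05 ± 0.06 and 0.04 ± 0.06 and were not called. Ccr1 changed by -2.25 ± 0.29. Cyp24a1 changed by -1.24 ± 0.33 and Tslp by -1.52 ± 0.34. The Cyp24a1 call ended without MC903 library 1, 2 or 3 or paeonol library 2 (edgeR adjusted p = 0.0579, 0.0637, 0.0782 and 0.0827), and the Tslp call without paeonol library 2 (0.0537). With the skeletal muscle covariate both calls ended (edgeR adjusted p = 0.15 and 0.128), and the Cyp24a1 call also without the expression filter and with the replicate number as a block (0.0571 and 0.0632). Il4 and Il13 were not called.

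Within the limits on expression and overlap given above, the largest increases besides Slurp1 were in Rdh9, a retinol dehydrogenase family gene (5.28 ± 0.79), Serpina3b (4.72 ± 0.31), Slurp2 (4.21 ± 0.60) and Krt77 (4.07 ± 0.66). Rdh9 had 9 to 16 estimated counts in the MC903 libraries and overlaps Rdh16f1 on the same strand, so its value is uncertain. Within the same limits, the largest decreases besides Chil3 and Ccl3 were in the acute phase gene Saa3 (-4.88 ± 1.06), the chemokine Ccl4 (-4.86 ± 0.52) and Tnfsf11, the cytokine RANKL (-4.59 ± 0.51). The Saa3 call ended without paeonol library 1 or 3 (edgeR adjusted p = 0.062 and 0.0574) and with the skeletal muscle covariate (0.0763).

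Epidermal differentiation and cornified envelope genes had 24 higher and 1 lower of 31 tested (25 and 1 adjusted over the list alone), with a median log2 change of 1.56. The late cornified envelope genes Lce1f and Lce1i changed by 1.74 ± 0.12 and 1.65 ± 0.12, and as members of a family of near-identical copies their separate values are uncertain. Tight junction genes had 7 higher and 0 lower of 13 tested (8 and 0 adjusted over the list alone), with claudin-1, Cldn1, at 1.00 ± 0.08 and Tjp3 at 2.03 ± 0.17. Epidermal lipid barrier genes had 13 higher and 3 lower of 24 tested (16 and 3 adjusted over the list alone), with the ceramidase Acer1 at 1.34 ± 0.15 and the sphingomyelinase Smpd1 at 1.33 ± 0.15. Sebaceous gland genes had 12 higher and 0 lower of 18 tested (13 and 0 adjusted over the list alone), and Dgat2 and Mgst1 changed by 1.74 ± 0.11 and 0.91 ± 0.14. Cartilage had 11 higher and 0 lower of 14 tested (11 and 0 adjusted over the list alone), with Sox9 at 0.86 ± 0.09 and Col11a2 at 0.93 ± 0.13. Adipocytes had 6 higher and 2 lower of 14 tested (7 and 2 adjusted over the list alone), and skeletal muscle 7 higher and 1 lower of 20 tested (8 and 1 adjusted over the list alone). These 7 lists were called higher with camera adjusted p from 2.01e-21 to 0.0111, and the adjusted p was between 0.278 and 0.64 with an estimated correlation. The skeletal muscle call ended without paeonol library 3, where the median log2 change went from 0.55 to 0.35 (camera adjusted p = 0.07), and with fry (fry adjusted p = 0.0977). It also ended with the skeletal muscle covariate (camera adjusted p = 0.893), which is the mean of that list and so takes out its change.

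Several immune lists and the endothelium list were lower with paeonol. Monocyte and macrophage markers had 1 higher and 16 lower of 20 tested (2 and 18 adjusted over the list alone), with a median of -1.51; the endotoxin co-receptor Cd14 changed by -2.48 ± 0.17 and the Fc receptor Fcgr3 by -1.64 ± 0.13. Chemokines had 1 higher and 12 lower of 31 tested (2 and 14 adjusted over the list alone), with Ccl6 at -2.65 ± 0.11. Neutrophil markers had 2 higher and 9 lower of 13 tested (2 and 9 adjusted over the list alone), with Csf3r at -1.93 ± 0.19 and Clec4d at -2.81 ± 0.33. Mast cell and basophil markers had 0 higher and 8 lower of 15 tested (0 and 9 adjusted over the list alone), with Hdc at -2.81 ± 0.14 and the tryptase Tpsb2 at -1.36 ± 0.19. Endothelium had 0 higher and 11 lower of 12 tested (0 and 11 adjusted over the list alone), with the adhesion molecules Selp at -1.73 ± 0.21 and Vcam1 at -1.79 ± 0.22. Stress keratins, alarmins and antimicrobial genes had 2 higher and 20 lower of 35 tested (2 and 25 adjusted over the list alone); Il33 changed by -0.70 ± 0.10, while the protease inhibitor Serpinb3a was higher, at 2.00 ± 0.15. NF-kB members and targets had 4 higher and 8 lower of 30 tested (4 and 10 adjusted over the list alone), TRP channels and itch receptors 4 higher and 9 lower of 23 tested (4 and 9 adjusted over the list alone), and NRF2 antioxidant genes 3 higher and 8 lower of 17 tested (4 and 9 adjusted over the list alone). Red blood cell genes had 0 higher and 4 lower of 5 tested (0 and 4 adjusted over the list alone). These 10 lists were called lower with camera adjusted p from 7.78e-21 to 0.0439, and the adjusted p was between 0.278 and 0.519 with an estimated correlation. The NRF2 call ended without MC903 library 1, paeonol library 1 or paeonol library 2 (camera adjusted p = 0.0835, 0.0552 and 0.0729), without the expression filter (0.0582) and with counts divided by 4 (0.0606), and the TRP channel call with the skeletal muscle covariate (0.0796).

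All 13 mitochondrially encoded genes were called lower with paeonol, and likewise adjusted over the list alone, with a median log2 change of -0.66. The respiratory chain genes mt-Nd1 and mt-Co2 changed by -0.88 ± 0.09 and -0.65 ± 0.08. The camera adjusted p was 3.68e-09, and the adjusted p = 0.31 with an estimated correlation. Mitochondrial genes made up 3.71% to 4.39% of the counts in the paeonol libraries, 6.54% to 6.79% in MC903 and 4.76% to 5.96% in control.

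The cell cycle list was not called, with 6 higher and 0 lower of 30 tested (5 and 0 adjusted over the list alone) and a median of 0.13. Without paeonol library 1 it was called higher (camera adjusted p = 0.0112, median 0.20). Type 2 cytokines and receptors had 4 higher and 10 lower of 23 tested (4 and 11 adjusted over the list alone) and a camera adjusted p of 0.0556, which passed the threshold without MC903 library 1 or 2, paeonol library 1 or 3, or control library 2 (between 0.0245 and 0.0457) and under scaling by library totals (0.0447). The remaining lists were also not called. Vitamin D receptor targets had 2 higher and 5 lower of 13 tested (2 and 5 adjusted over the list alone), type 17 and type 1 cytokines 2 higher and 3 lower of 16 tested (2 and 3 adjusted over the list alone), and interferon-stimulated genes 0 higher and 1 lower of 24 tested (0 and 0 adjusted over the list alone). Immediate early and heat shock genes had 4 higher and 4 lower of 16 tested (4 and 5 adjusted over the list alone), T cells 2 higher and 6 lower of 19 tested (2 and 7 adjusted over the list alone), and dendritic and Langerhans cells 5 higher and 3 lower of 17 tested (5 and 4 adjusted over the list alone). Fibroblast and matrix genes had 6 higher and 7 lower of 19 tested (6 and 7 adjusted over the list alone), hair follicle genes 3 higher and 1 lower of 18 tested (3 and 1 adjusted over the list alone), nerve and Schwann cells 4 higher and 1 lower of 12 tested (4 and 1 adjusted over the list alone), and eosinophils 1 higher and 0 lower of 4 tested (1 and 0 adjusted over the list alone). No B or plasma cell marker of 10 was called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05. Some of these lists passed the threshold with 1 library left out. By camera adjusted p, these were T cells without MC903 library 1 (0.0245), interferon-stimulated genes without MC903 library 2 (0.0197), and fibroblasts without paeonol library 1 (0.0466). The others were vitamin D receptor targets without paeonol library 1 or 3 (0.034 and 0.0308) and nerve without paeonol library 3 or control library 1 (0.0308 and 0.0456). The median and the direction of the test differed in sign for the immediate early and the dendritic cell lists.

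Both comparisons above share the MC903 libraries, and the genes that went one way with MC903 and the other way with paeonol were counted. Chil3 rose by 5.62 ± 0.53 with MC903 and changed by -5.77 ± 0.53 with paeonol. Its paeonol level differed from control by -0.16 ± 0.54 and was not called; with the skeletal muscle covariate the call of its rise with MC903 ended (edgeR adjusted p = 0.37). AL805899.1 fell from 58.1 ± 3.61 to 8.22 ± 1.78 CPM, still at least 40.5-fold above the control floor, and Ecel1 fell from 78.8 ± 22.2 to 5.8 ± 3.81 CPM. Serpina3b and Krt77, lowered by MC903, rose with paeonol to 10.8 ± 1.12 and 17.4 ± 9.85 CPM, beside 46.6 ± 14.7 and 52.5 ± 23.9 CPM in control.

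Of the genes raised by MC903, 2385 (47.3%) were called lower with paeonol, and of those lowered, 2564 (49.2%) were called higher, 4949 in all. Calls with the same sign in both numbered 172. Lists of these sizes drawn independently would share 724 and 798 genes in opposite directions and 1520 in the same direction. In 20 simulations of unchanged groups that shared the MC903 libraries, edgeR called on average 0.25 and 0.6 genes in the 2 comparisons, too few to give opposite calls, so the simulations bear only on the values that follow. Over all genes tested, the log2 changes had a correlation of -0.736, against -0.502 ± 0.012 (SD) in the simulations, and a covariance of -0.918 against -0.104, a difference of -0.814. Part of the excess over the independent lists may come from the shared MC903 libraries. These values are across genes, which are not independent replicates. Of the genes called in MC903 versus control, 4980 were also called with the same sign in paeonol versus control, 4929 were not called there, and 350 were called with the opposite sign. These 2 comparisons share the control libraries, and their calls were not set beside unchanged groups.

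**Figure D3:**
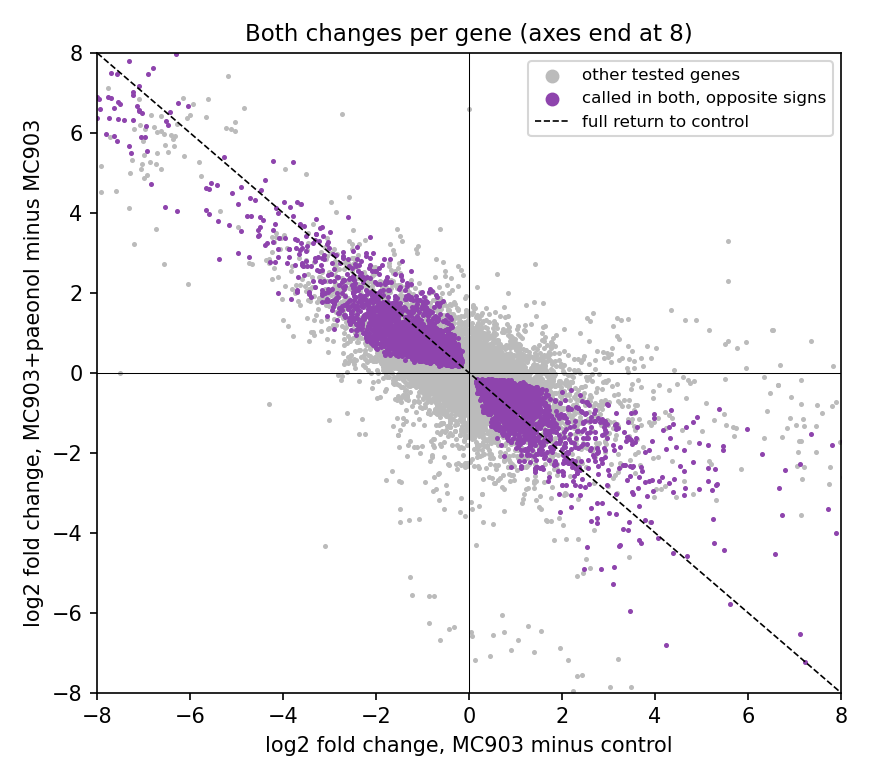
Each point is 1 of the tested genes, with the log2 fold change of MC903 against control on the horizontal axis and of MC903 with paeonol against MC903 on the vertical axis; the dashed line marks a full return to control, and 58 genes lie outside the axes, which end at 8. The 4949 genes called in both with opposite signs, in purple, lie at the upper left (2564 genes) and lower right (2385 genes).

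The last comparison, MC903 with paeonol against control, shows what differed from control when both were given. Cell cycle genes, stress keratins and epidermal differentiation genes were mostly higher, and muscle, fat, nerve and blood genes mostly lower. Rptn, a cornified envelope protein, went from 12.5 ± 1.11 CPM in control to 1480 ± 792 CPM with both treatments (SD, n = 3), a log2 change of 6.89 ± 0.45. The beta-globin gene Hbb-bs went from 34.7 ± 10.7 to 1.15 ± 0.638 CPM, a log2 change of -4.90 ± 0.49. Of 21925 genes, edgeR called 6765, 3578 higher and 3187 lower. With scaling by library totals alone the split was 2155 higher and 5354 lower, and the median log2 change of all genes moved from -0.0347 to -0.197.

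Trpv3 stood at 84.9 ± 15.6 CPM against 52.5 ± 4.89 in control, a log2 change of 0.69 ± 0.12 with an edgeR adjusted p of 0.00189. Ccl3 was below control, at 0.538 ± 0.19 against 2.27 ± 0.926 CPM, a log2 change of -2.07 ± 0.37 with an edgeR adjusted p of 0.00187. Cyp24a1 and Tslp remained above control by 7.61 ± 0.43 and 5.83 ± 0.42. Nfkb1, Rela and Nfkbia were higher by 0.19 ± 0.06, 0.23 ± 0.06 and 0.47 ± 0.13, and under scaling by library totals the 3 calls ended, with log2 changes of 0.03, 0.07 and 0.31. The Nfkb1 call also ended without paeonol library 2 or 3 or control library 2 or 3 (edgeR adjusted p between 0.0634 and 0.104), and the Nfkbia call without control library 1 or 3 (0.057 and 0.0829). Without paeonol library 3 the Nfkbia log2 change was 0.29. With the skeletal muscle covariate the calls of Trpv3, Ccl3, Nfkb1, Rela, Nfkbia and Tslp ended (edgeR adjusted p = 0.172, 0.215, 0.938, 0.506, 0.372 and 0.0508), and a minimum of 2-fold ended those of Trpv3, Nfkb1, Rela and Nfkbia. Ccr1, Il4 and Il13 had log2 changes of -0.24 ± 0.28, -1.01 ± 0.37 and -0.58 ± 0.96 and were not called. Without control library 2, Ccr1 had a log2 change of 0.13. Il4 passed the threshold under scaling by library totals (edgeR adjusted p = 0.0323).

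Akr1d1, with 6 to 9 estimated counts in the control libraries, was at 61.5 ± 32.7 CPM with paeonol, 462 times control (95% counting interval 212 to 1260). S100g was at 5.02 ± 4.11 CPM, at least 24.8-fold above the floor of the controls, which had no counts, and at least 14.2-fold without paeonol library 3. Within the limits on expression and overlap, globin genes led the decreases, with Hbb-bt at -4.96 ± 0.75, Hba-a2 at -4.47 ± 0.67 and Hba-a1 at -3.36 ± 0.44. These are pairs of closely similar genes, so their separate values are uncertain. The lipid desaturase Scd3 changed by -2.66 ± 0.54. The calls of S100g, Hbb-bs, Hba-a2, Hba-a1 and Scd3 ended with the skeletal muscle covariate (edgeR adjusted p = 0.0767, 0.0562, 0.0943, 0.0887 and 0.948).

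Cell cycle genes had 30 higher and 0 lower of 30 tested (30 and 0 adjusted over the list alone), with a median log2 change of 0.88; Mcm5 and the ribonucleotide reductase gene Rrm2 rose by 1.37 ± 0.10 and 1.34 ± 0.10. Epidermal differentiation genes had 24 higher and 0 lower of 31 tested (25 and 1 adjusted over the list alone), with the transglutaminase Tgm3 at 1.53 ± 0.11 and the caspase Casp14 at 2.13 ± 0.14. Stress keratins, alarmins and antimicrobial genes had 22 higher and 0 lower of 35 tested (24 and 0 adjusted over the list alone), with Serpinb3a at 2.84 ± 0.16. Epidermal lipid barrier genes had 16 higher and 0 lower of 24 tested (16 and 0 adjusted over the list alone), with Abhd5 at 0.75 ± 0.07 and the glucosylceramide synthase Ugcg at 0.98 ± 0.11. NRF2 antioxidant genes had 11 higher and 2 lower of 17 tested (11 and 2 adjusted over the list alone), with G6pdx at 1.11 ± 0.08 and Srxn1 at 1.14 ± 0.09. Vitamin D receptor targets had 7 higher and 1 lower of 13 tested (7 and 1 adjusted over the list alone), immediate early and heat shock genes 10 higher and 0 lower of 16 tested (10 and 0 adjusted over the list alone), hair follicle genes 5 higher and 0 lower of 18 tested (5 and 0 adjusted over the list alone), and tight junctions 5 higher and 1 lower of 13 tested (7 and 1 adjusted over the list alone). These 9 lists were called higher with camera adjusted p from 6.88e-37 to 0.032, and the adjusted p was between 0.0762 and 0.574 with an estimated correlation. The hair follicle call ended without paeonol library 2 or control library 3, where the median log2 change turned from 0.13 to -0.47 and -0.15 (camera adjusted p = 0.107 and 0.0819), and the tight junction call without paeonol library 3 or control library 2 (camera adjusted p = 0.0514 and 0.0632). With fry the hair follicle call ended too (fry adjusted p = 0.0605). Under scaling by library totals the hair follicle call stayed, although the median turned below 0. The tight junction call also ended with the skeletal muscle covariate (camera adjusted p = 0.659), as did the calls of Abhd5 and Ugcg (edgeR adjusted p = 0.104 and 0.0961).

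Skeletal muscle genes had 0 higher and 20 lower of 20 tested (0 and 20 adjusted over the list alone), with Mb at -1.09 ± 0.12 and the calcium release channel Ryr1 at -0.94 ± 0.12. Nerve and Schwann cell markers had 0 higher and 10 lower of 12 tested (0 and 10 adjusted over the list alone), with Mbp at -0.94 ± 0.06. Adipocytes had 0 higher and 12 lower of 14 tested (0 and 13 adjusted over the list alone), with Adipoq at -1.25 ± 0.14 and Plin1 at -1.39 ± 0.17. Red blood cell genes had 0 higher and 5 lower of 5 tested (0 and 5 adjusted over the list alone). Cartilage had 0 higher and 7 lower of 14 tested (0 and 8 adjusted over the list alone), with Col11a2 at -1.27 ± 0.12 and Col9a3 at -0.89 ± 0.10. Fibroblast and matrix genes had 2 higher and 12 lower of 19 tested (2 and 15 adjusted over the list alone), with the collagen gene Col1a2 at -0.93 ± 0.12 and decorin, Dcn, at -0.78 ± 0.12. Endothelium had 0 higher and 10 lower of 12 tested (0 and 11 adjusted over the list alone), with the receptors Tek at -0.78 ± 0.12 and Kdr at -0.75 ± 0.11. Monocytes and macrophages had 1 higher and 10 lower of 20 tested (1 and 11 adjusted over the list alone), dendritic and Langerhans cells 0 higher and 9 lower of 17 tested (0 and 9 adjusted over the list alone), sebaceous gland 0 higher and 5 lower of 18 tested (0 and 5 adjusted over the list alone), and mitochondrially encoded genes 0 higher and 8 lower of 13 tested (0 and 11 adjusted over the list alone). These 11 lists were called lower with camera adjusted p from 2.1e-15 to 0.0311, and the adjusted p was between 0.0971 and 0.694 with an estimated correlation. The sebaceous gland call ended without paeonol library 1 or 2 or control library 3 (camera adjusted p between 0.0693 and 0.096). With fry the calls of sebaceous gland (fry adjusted p = 0.164), monocytes and macrophages (0.0633) and mitochondrially encoded genes (0.0633) ended. The skeletal muscle covariate ended the list calls of skeletal muscle, sebaceous gland and mitochondrially encoded genes (camera adjusted p = 0.965, 0.552 and 0.231). Single-gene calls that ended with the skeletal muscle covariate were those of Mb, Ryr1, Adipoq, Plin1, Col11a2, Col9a3, Col1a2, Dcn, Tek and Kdr (edgeR adjusted p between 0.0599 and 0.613). For the skeletal muscle list, Mb and Ryr1 this follows from the covariate, which is the mean of that list.

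The other lists were not called against control. Type 2 cytokines and receptors had 5 higher and 1 lower of 23 tested (4 and 0 adjusted over the list alone), chemokines 2 higher and 7 lower of 31 tested (1 and 5 adjusted over the list alone), and NF-kB members and targets 8 higher and 1 lower of 30 tested (8 and 1 adjusted over the list alone). TRP channels and itch receptors had 5 higher and 4 lower of 23 tested (5 and 4 adjusted over the list alone), type 17 and type 1 cytokines 1 higher and 3 lower of 16 tested (1 and 3 adjusted over the list alone), mast cells and basophils 0 higher and 1 lower of 15 tested (0 and 0 adjusted over the list alone), neutrophils 1 higher and 2 lower of 13 tested (1 and 2 adjusted over the list alone), and T cells 1 higher and 3 lower of 19 tested (1 and 3 adjusted over the list alone). No member of the interferon-stimulated (24 tested), eosinophil (4) or B cell (10) lists was called by edgeR. At an unadjusted p under 0.05 there was 1 higher and 1 lower interferon-stimulated gene, 1 higher eosinophil gene and 0 B cell genes, and DESeq2 called 1 interferon-stimulated gene lower and 0 genes of the others. With 1 library left out, some lists passed the threshold by camera adjusted p. These were NF-kB members and targets (paeonol library 2, 0.0266; control library 2, 0.000629), interferon-stimulated genes (control library 2, 0.00435) and chemokines (paeonol library 1, 0.0476; control library 1, 0.0328; control library 3, 0.0162). T cells and B cells did so without paeonol library 2 (0.042 and 0.0421). The median and mean of the eosinophil list differed in sign.

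Several of the named genes overlap another tested gene on the opposite strand, and whether the counting used strand is not given in the sources used here, so their values may include reads of the partner. These are Cyp24a1 (Pfdn4), S100g (Ctps2), Mb (Apol6), Mbp (Rpl21-ps8), Slurp1 (Them6), Ccl6 (E230016K23Rik), Selp (Gm16548), Tjp3 (Apba3), Acer1 (AC073683.1), Abhd5 (A730085K08Rik), Col9a3 (Tcfl5) and G6pdx (Ikbkg). On the same strand, Akr1d1, Gsr, mt-Nd1, Rptn and Col1a2 overlap tested features (Gm7463, Gm24727, mt-Ti, Gm37857 and Gm43921). Trpv3, Ccl3 and Nfkbia overlap none in GENCODE M21.

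**Figure D4:**
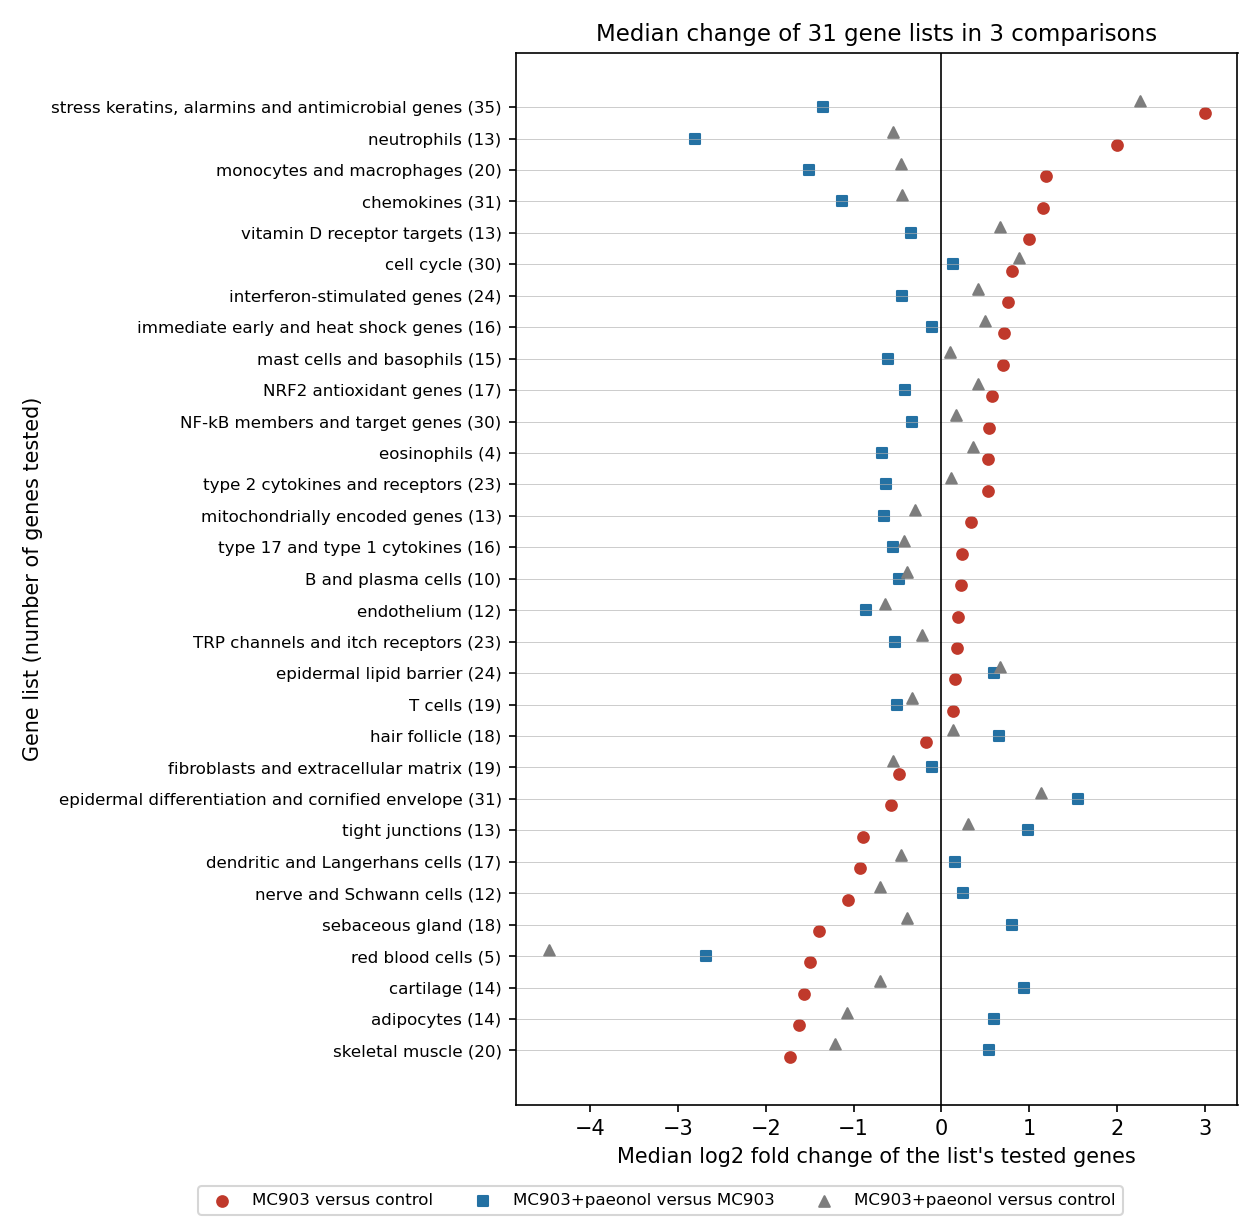
Each line is 1 of 31 gene lists with its number of tested genes, and each symbol the median log2 fold change of those genes in 1 of the 3 comparisons. Cell cycle genes have a median of 0.81 in MC903 and 0.88 with paeonol against control, while monocyte and macrophage markers have medians of 1.19 in MC903 and -0.46 with paeonol against control.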

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

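In all, 24 alternatives were run, not each on every result. Of 128 named-gene results, 71 came out the same in all those run on them, and of 93 list results 59 did, leaving aside the estimated correlation and fry. Counts divided by 4 and library totals alone were chosen after the data were seen. The skeletal muscle covariate is nearly a function of the group (R squared 0.92), so the fit has little left to separate the groups. With it, 1065 genes (626 higher, 439 lower), 3886 (2082 and 1804) and 323 (273 and 50) were called in the 3 comparisons, 909 changed in opposite directions, and 12 lists were called in MC903 versus control; 43 named-gene calls ended with the sign kept, and 10 list calls with the direction of the list test kept, although for mast cells and basophils in MC903 versus control the median turned to -0.0242. Values that turned sign with it were Il13 (1.98 in MC903 and 2.15 with paeonol against control) and Nfkb1 with paeonol against MC903 (0.0208). The direction of the list test turned with it for skeletal muscle in the 3 comparisons (medians -0.0377, -0.0117 and 0.0116), and with paeonol against control for sebaceous gland (0.0421) and mitochondrially encoded genes (0.158). The covariate is the mean log2 CPM of the skeletal muscle list, so the changes of that list lie near 0 by construction. The calls that ended for this list and its members therefore say nothing about muscle genes. A minimum of 2-fold left 3733 genes (1502 higher, 2231 lower), 1858 (1002 and 856) and 1257 (653 and 604), and 1332 opposite changes; it ended 24 named-gene calls, each with a log2 change under 1 in size. An estimated correlation left 0, 0 and 0 lists (fry 22, 20 and 16). Library totals alone gave 2155 higher and 5354 lower with paeonol against control. DESeq2 called 10703, 7115 and 7397 genes, and counts divided by 4 gave 10225, 6673 and 7130 genes and 16, 17 and 20 lists.

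With the replicate number as a block, 10104, 6348 and 6673 genes were called. No clear pairing by number was seen. Residual correlations of libraries with the same number lay between -0.0113 and 0.04, others between -0.0322 and 0.0255, and 3 of 9 libraries correlated best with their own number. These values do not show that the samples are unpaired. With 1 library left out, the paeonol-against-control change of Ccr1 ranged from -0.48 (without paeonol library 1) to 0.13 (without control library 2). Measured against MC903 library 2, left out of the choice of genes, those lowered in MC903 had a median paeonol change of 0.374 (0.441 with all libraries). The cause of these shifts was not tested.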

Other observations

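Families chosen after the data were seen are described next. Several Lce1 genes belong to the epidermal differentiation list above, and the Lce3 and several Sprr genes to the stress keratin list. Their values here are therefore not separate from the results of those lists. The late cornified envelope genes lie together on chromosome 3 (GRCm38, Lce1 from 92646535 to 93019060, Lce3 from 92925287 to 92993426), with the Lce3 span inside the Lce1 span. Of 14 Lce1 genes, 12 were lower in MC903 than in control (median log2 change -0.85) and 14 were higher with paeonol than with MC903 (1.68). Of 6 Lce3 genes, 6 were higher in MC903 (2.54) and 6 lower with paeonol (-1.58). Of 14 Sprr genes, cornified envelope precursors, 12 were higher in MC903 (3.42), and with paeonol 0 were called higher and 1 lower by edgeR; their median of -0.0085 turned to 0.0105 under scaling by library totals. Of 17 cholesterol synthesis genes, 13 were higher with paeonol than with MC903 (0.53).

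Of 12 genes that glucocorticoids are known to induce, also chosen after the data were seen, 11 were higher in MC903 (median log2 change 1.03) and 12 lower with paeonol (-1.08). Fkbp5, a chaperone of the glucocorticoid receptor, changed by 1.72 and -2.18. Of 78 cytosolic ribosomal protein genes, 73 were higher and 1 lower in MC903 (median 0.67). With paeonol 62 were lower and 1 higher (median -0.30). Of 44 collagen genes, 33 were lower and 6 higher in MC903 (median -1.43). With paeonol 25 were higher and 5 lower (median 0.67).

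Opposite changes: the counts over splits and the measurement against a left-out MC903 library were planned, while the bound set on the latter and the other tests in this paragraph were chosen after the result was seen. Of 100 splits of the 9 libraries into 3 groups, 1, the real one, gave at least 4949 opposite changes (highest other 2877). Such a count was thus rare among groupings of these libraries. Splits that mix differing groups have a larger spread within groups and so few calls of any kind. The rarity therefore shows that the groups differ and is not particular to opposite changes. The labels do not say whether the libraries came from separate animals, so differences between animals or in handling are not excluded. The shared MC903 libraries are argued against as the whole cause. With genes chosen without the MC903 library they were measured against, the raised genes had a median paeonol change of -0.272 or lower. A common weaker response would leave each list the same share of its MC903 change only if the log2 changes of all lists scaled alike with its strength. That condition was not tested. The cell cycle list kept 117 ± 16.6% of its change against -44.3 ± 34.5% for monocytes and macrophages (SD, n = 3), at least 109 points apart. These 2 lists were picked after their changes were known. They argue against a common share for these 2 lists only, and several other lists kept shares between them. Dilution by a changed share of immune cell RNA would move epidermal genes together, whereas Lce3 (-1.58) and Lce1 (1.68) genes moved apart. Both families were chosen after their changes were seen. Their values show only that less dilution by immune cell RNA does not account for the fall of the Lce3 genes. Whether it accounts for the rise of the Lce1 genes stays open. A loss of signals from immune cells to keratinocytes was not tested and stays open. An action of paeonol on several cell types stays open as an untested hypothesis.

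Lower skeletal muscle, cartilage and adipocyte genes in MC903: all tests in this paragraph were chosen after the result was seen. A smaller share of RNA from the deeper tissues may account for these, since the 3 medians (-1.73, -1.57 and -1.62) lie within 0.166 of each other, against a standard error of 0.79; this is a weak test and does not separate less tissue from lower expression within it. A single dilution of all tissue other than epidermis is argued against by endothelium (0.195), 1.93 above skeletal muscle, although a change in endothelium itself stays open. The highest of the 3 medians over 3 scalings was -1.56, so the choice among these scalings does not account for the decrease. The TMM factors span only 0.942 to 1.09, so these scalings could not bring the medians near 0. Whether another scaling would do so was not tested. A direct effect of MC903 on these tissues was not tested.

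Lower mitochondrially encoded transcripts with paeonol: all tests in this paragraph were chosen after the result was seen. The 13 genes had a median log2 change of -0.66, whereas nuclear-encoded respiratory chain genes had one of -0.0439, which argues against lower expression of the whole chain. Skeletal muscle, rich in mitochondria, had a median of 0.546, which argues against a smaller share of muscle. RNA handling or library preparation cannot be told apart from the groups: the highest mitochondrial share in the paeonol libraries was 4.39%, below the lowest in MC903, and no batch or quality value per library is used here. An effect of paeonol on mitochondrial transcripts stays open as untested.

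The splits of the 6 libraries of each comparison, planned before the result was seen, are 10, too few for a share under 0.05. At least as many genes as in the real split (10243, 5990 and 6610, in fits of 2 groups) were called by edgeR in 1, 1 and 1 of the 10, the highest other being 0 each time. Those others had up to 313, 466 and 470 genes at an unadjusted p under 0.05. At least as many lists as in the real split (17, 19 and 20) were called in 3, 3 and 2 of the 10, the highest other being 21, 20 and 22.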
